A study of Mus musculus with 8 samples.

How the data were processed

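Bulk RNA sequencing was carried out on Langerhans cells, the dendritic cells of the epidermis, sorted from ear skin of wild-type and Ezh2 knockout C57BL/6 mice. Per the labels' protocols, the epidermis was separated with dispase and digested with collagenase, and live CD45+ MHC class II+ CD24+ EpCAM+ cells negative for Ly6G and CD103 were sorted. Per the submitters' processing notes, STAR 2.5.2b and featureCounts 1.5.0 were used with genome build GRCm38 (mm10). The annotation release, the strand setting and the treatment of read pairs were not given in the sources used here. The deposited values are raw counts of reads per gene for 25247 Ensembl genes in 8 libraries, with no normalization by the authors that the values show. Library totals ranged from 11051402 to 18966195 counts, and 0 columns were left unused. Among counts from 1 to 20, 60.1% were even, so the mates of a pair may have been counted separately, and intervals from counting error are then too narrow.

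The group of 4 of the 8 libraries was open. Each column of the table carries a library code. The code in a sample's title and the code in its description agreed for RMN030 and RMN031 (wild-type replicates 1 and 2) and for RMN038 and RMN039 (knockout replicates 3 and 4). For RMN032 and RMN033 the titles gave knockout and the descriptions wild type, and for RMN036 and RMN037 the titles gave wild type and the descriptions knockout. Before the data were examined, 3 fits were fixed, all to be reported side by side with none preferred by its result: the undisputed libraries (2 against 2), the title-code reading (4 against 4) and the description-code reading (4 against 4). The codes form an earlier run (030 to 033) and a later run (036 to 039). In the undisputed libraries and in the description-code reading the genotype coincides with the run, so that no fit can separate them. The title-code reading has 2 libraries of each genotype in each run. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise (lowest chi-square per gene 11.7).

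Symbols were assigned by unversioned Ensembl identifier from a table of mouse gene names, in which 25080 identifiers matched and 167 did not, and coordinates and gene types came from a GENCODE annotation of GRCm38. CPM values are counts scaled to the column total. Differential expression was computed with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, robust quasi-likelihood fits and two-sided F-tests, knockout minus wild type, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 fold changes are standard errors (SE) derived from the F statistic, and those of CPM are standard deviations (SD). Levels of one quantity per library were compared with exact two-sided permutation tests. The 25 gene lists fixed beforehand covered Polycomb repressive complex 2 (PRC2), its classical targets, Langerhans cell identity, adhesion, actin, dendritic cell migration, MHC class II, MHC class I, TGF-beta, interferon-stimulated genes, inflammation, cell cycle, apoptosis, dissociation response, glycolysis, oxidative phosphorylation, cholesterol synthesis, keratinocytes, T cells, monocytes and macrophages, dermal dendritic cells, granulocytes and mast cells, fibroblasts with endothelial cells and melanocytes, blood, and sex. Of these, 24 with at least 3 tested members entered limma 3.58.1 camera tests with a preset inter-gene correlation of 0.01, adjusted over the lists of a fit. Camera with an estimated correlation and fry were the checks.

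Genes were named by a rule set beforehand: Ezh2 and Tln1, up to 10 higher and 10 lower genes per fit with the smallest p among those past the threshold (unnamed models and pseudogenes left out), and up to 4 list members with the smallest p. Other genes named are marked as chosen after their values were seen. Alternatives were RLE size factors, no filter, a filter at 1 CPM, DESeq2 1.42.0, limma voom with quality weights, each library left out, the replicate number as a block and the code run as a covariate. Added after the data were seen were fits without RMN030 and RMN031, without T lineage genes, and within each code run. Leaving out a library of the undisputed fit leaves 1 library in a group, which is then assumed to vary like the other group.

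The edgeR step was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn only from those above a minimum mean count, so the recovery does not hold for genes of low level. No difference between code runs was simulated. It recovered 41% and 82% of them in the undisputed design (14192 genes), 60% and 94% in the title-code design (14278 genes), and 60% and 96% in the description-code design (14290 genes). Of its calls, 15 of 138, 14 of 168 and 11 of 167 were false in these designs, a larger share than the threshold of 0.05. For DESeq2 the false calls were 16 of 147, 38 of 204 and 45 of 212. Intervals and floors cover counting error only, and the floor for a group at 0 was 3 counts over the group. Haemoglobin and Hspa1 gene copies, and mitochondrial genes with nuclear copies, share reads and their values are uncertain as single genes.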

Results

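The libraries measured gene expression in sorted epidermal Langerhans cells of wild-type (WT) and Ezh2 knockout (KO) mice. Ezh2 is the histone H3K27 methyltransferase of PRC2, and the series asked how it affects Langerhans cell migration and allergic contact dermatitis. The total counts were 13095298 in RMN030, 18565072 in RMN031, 16318784 in RMN032 and 18966195 in RMN033. They were 14874624 in RMN036, 16683638 in RMN037, 14078333 in RMN038 and 11051402 in RMN039. Because titles and descriptions disagree on RMN032, RMN033, RMN036 and RMN037, each comparison is given for the 4 undisputed libraries and for both readings of all 8.

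Ezh2 (ENSMUSG00000029687, GRCm38 chromosome 6, 47530139 to 47595341, minus strand) was detected in every library. Its level was 15.7 CPM in RMN030, 22.4 in RMN031, 15.2 in RMN032, 14.9 in RMN033, 19.0 in RMN036, 17.6 in RMN037, 12.7 in RMN038 and 10.5 in RMN039. In the undisputed libraries it was 19.0 ± 4.7 CPM in WT and 11.6 ± 1.6 in KO (SD, n = 2 each), a log2 fold change of -0.66 (SE 0.31, adjusted p = 0.455). By title code it was 18.6 ± 2.8 in WT and 13.3 ± 2.2 CPM in KO with no overlap (SD, n = 4 each, exact permutation p = 0.0286, the smallest this design allows). The edgeR log2 fold change was -0.49 (SE 0.18), with an adjusted p over all genes of 0.998. Within the earlier and later code runs the log2 fold changes were -0.37 (SE 0.26) and -0.63 (SE 0.26). By description code it was 17.0 ± 3.6 in WT and 14.9 ± 4.0 in KO (exact permutation p = 0.457, n = 4 each). These counts cover the whole gene, and the deleted part is not given in the labels, so residual transcript does not test the deletion.

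Tln1 (ENSMUSG00000028465, chromosome 4, 43531519 to 43562691, minus strand) encodes talin 1, which links integrins to actin and is a cytoplasmic partner of Ezh2. It passed the threshold in none of the 3 edgeR fits. Its log2 fold change was -0.36 (SE 0.14, adjusted p = 0.339) in the undisputed libraries, -0.12 (SE 0.11, adjusted p = 0.998) by title code and -0.25 (SE 0.09, adjusted p = 0.202) by description code. Its CPM by description code was 662 ± 35.5 in WT and 539 ± 52.4 in KO (exact permutation p = 0.0286, n = 4 each), a split that is also that of the code runs.

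**Figure D1:**
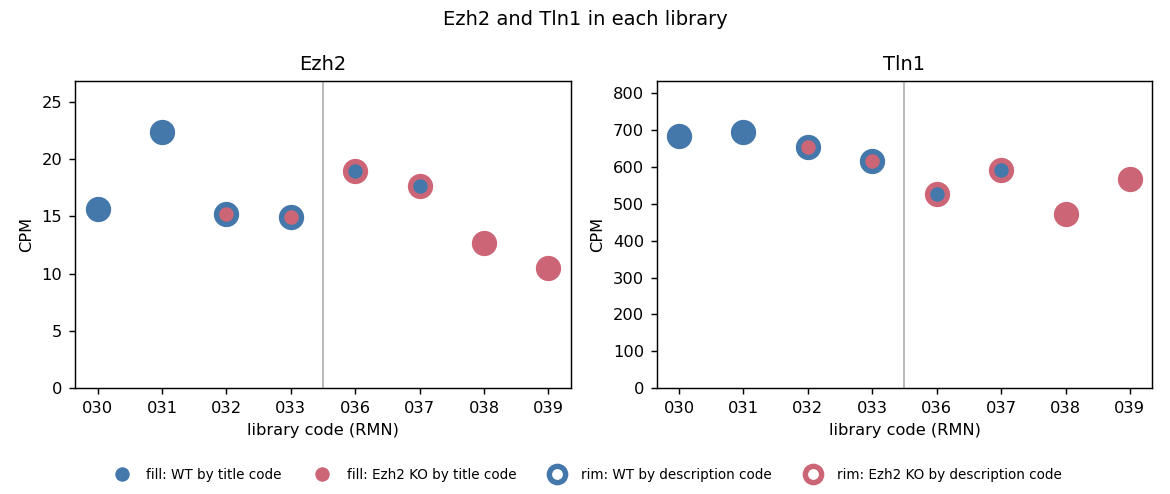
CPM of Ezh2 (left) and Tln1 (right) in each library, 1 point per library; fill colour is the genotype by title code, rim colour that by description code, and the vertical line parts the earlier from the later library codes. Ezh2 ranges from 10.5 CPM in RMN039 to 22.4 CPM in RMN031, and points whose fill and rim differ are the 4 disputed libraries.

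In the undisputed libraries, blood marker transcripts were higher and T cell marker transcripts far lower in KO. The haemoglobin genes Hbb-bt, Hbb-bs, Hba-a2 and Hba-a1, the globin chains of red blood cells, were 9.76-, 9.49-, 9.94- and 10.1-fold higher in KO. Alas2, the first enzyme of erythroid haem synthesis, was 14.6-fold higher (adjusted p = 5.3e-05). The mitochondrially encoded cytochrome oxidase genes mt-Co3 and mt-Co1 were 2.81- and 2.84-fold higher, the tight junction gene Cldn4 2.84-fold, and the stress-induced chaperone genes Hspa1a and Hspa1b, near-identical copies that share reads, 2.34- and 2.29-fold. Lower in KO were the T cell receptor constant genes Trbc2 (50.1 ± 7.3 against 1.41 ± 0.18 CPM, SD, n = 2 each) and Trbc1 (46.9-fold), the T cell kinase gene Lck (24.0-fold) and the T cell transcription factor gene Tcf7 (24.0-fold). With 0 counts in both KO libraries, Dntt, which adds nucleotides to rearranging antigen receptor genes, was at least 221-fold lower, Cd8b1 at least 155-fold, the adaptor gene Lat at least 155-fold, the thymus-homing receptor gene Ccr9 at least 144-fold and Rhoh at least 132-fold. Cd8a had 510 counts in WT and 2 in KO, a ratio of 202 (95% counting interval 55.7 to 1676). In all, 117 of 14727 genes passed, 66 higher and 51 lower.

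Of the gene lists, T cell markers fell as a group in the undisputed libraries: 9 of 19 tested members were lower and 0 higher, and 14 were lower when adjusted over the list alone (camera adjusted p = 5.5e-17; adjusted p = 0.429 with an estimated correlation). Blood markers rose (5 of 6 members, and 5 adjusted over the list alone; adjusted p = 1.2e-08, and 0.429 as the adjusted p with an estimated correlation). Mast cell and granulocyte markers rose (adjusted p = 6.6e-05; adjusted p = 0.429 with an estimated correlation), with 1 of 9 members called, the mast cell protease gene Mcpt4 at 0.391 against 6.28 CPM, and 6 adjusted over the list alone. Mcpt4 did not pass with limma voom (adjusted p = 0.0878). Fibroblast, endothelial and melanocyte markers had 3 of 15 members higher, and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0266; adjusted p = 0.730 with an estimated correlation): the matrix genes Dcn (4.57-fold), Sparc (3.43-fold) and Lum, which did not pass with limma voom (adjusted p = 0.189). Monocyte and macrophage markers had 3 of 20 higher, and 5 higher and 2 lower adjusted over the list alone (adjusted p = 0.0461; adjusted p = 0.730 with an estimated correlation): lysozyme Lyz2 (2.01-fold), coagulation factor gene F13a1 (3.17-fold) and scavenger receptor gene Cd163 (4.40-fold). In the adhesion list the leukocyte integrin gene Itgal was 8.60-fold lower (1 of 35 members, and 1 adjusted over the list alone). Like the T cell markers, it was high in RMN030 and RMN031 (14.3 and 14.6 CPM) and at 1.99 CPM or less in the 6 other libraries. In the actin list Rhoh and Rac2 (5.51-fold), both also highest in RMN030 and RMN031, were lower and Rac1 was 2.62-fold higher (3 of 40, and 3 higher and 3 lower adjusted over the list alone). Rac1 did not pass with DESeq2 (adjusted p = 0.104) or limma voom (adjusted p = 0.0624), and by title code it was lower in KO within the earlier code run (log2 fold change -1.83, adjusted p = 0.00666). Keratin gene Krt79 rose from 64.4 to 125 CPM (1 of 24 keratinocyte list members higher) and Trp63, a transcription factor of basal keratinocytes, was 1.74-fold lower (1 of 24), with 4 higher and 1 lower adjusted over the list alone. In the dissociation response list, Hspa1a and Hspa1b were higher and the immediate early gene Nr4a1 1.55-fold lower (3 of 32, and 8 higher and 5 lower adjusted over the list alone). The 7 other chaperone genes of that list, looked up after the data were seen, did not pass over all genes. Their log2 fold changes ranged from -0.11 (Hspb1) to 0.44 (Dnaja1), and Dnaja1 and Hsp90aa1 (0.40) passed when adjusted over the list alone. No member of the PRC2, Langerhans cell identity or dendritic cell migration lists passed in edgeR with the filter on low counts. Of the identity genes, Runx3, which Langerhans cells need to develop, was at 313 ± 21 CPM in WT and 210.5 ± 12.3 in KO (edgeR adjusted p = 0.151, 0.0357 as the adjusted p without a filter, DESeq2 adjusted p = 0.0279), and Tgfbr2 had a log2 fold change of 0.57 (edgeR adjusted p = 0.180, DESeq2 adjusted p = 0.0448). Of the migration genes, the matrix protease gene Mmp9 had a log2 fold change of -0.56 (edgeR adjusted p = 0.0850). Its adjusted p was 0.00688 without a filter, 0.00274 with DESeq2 and 0.0293 with limma voom. Socs2 had a log2 fold change of 1.92 (edgeR adjusted p = 0.127, and 0.0143 without a filter). Adjusted over the list alone, 2 migration genes were higher and 1 lower, and 0 PRC2 or identity genes passed. The mitochondrial share of counts was 1.36 ± 0.48% in WT and 3.81 ± 0.08% in KO (SD, n = 2 each), and genotype here coincides with the code run. DESeq2 called 305 genes, a fit without a filter 440, and fits without RMN030, RMN031, RMN038 or RMN039 called 263, 629, 342 and 435. Lum, Nr4a1, Trp63 and Rac1 lost their call without at least 1 of the libraries.

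**Figure D2:**
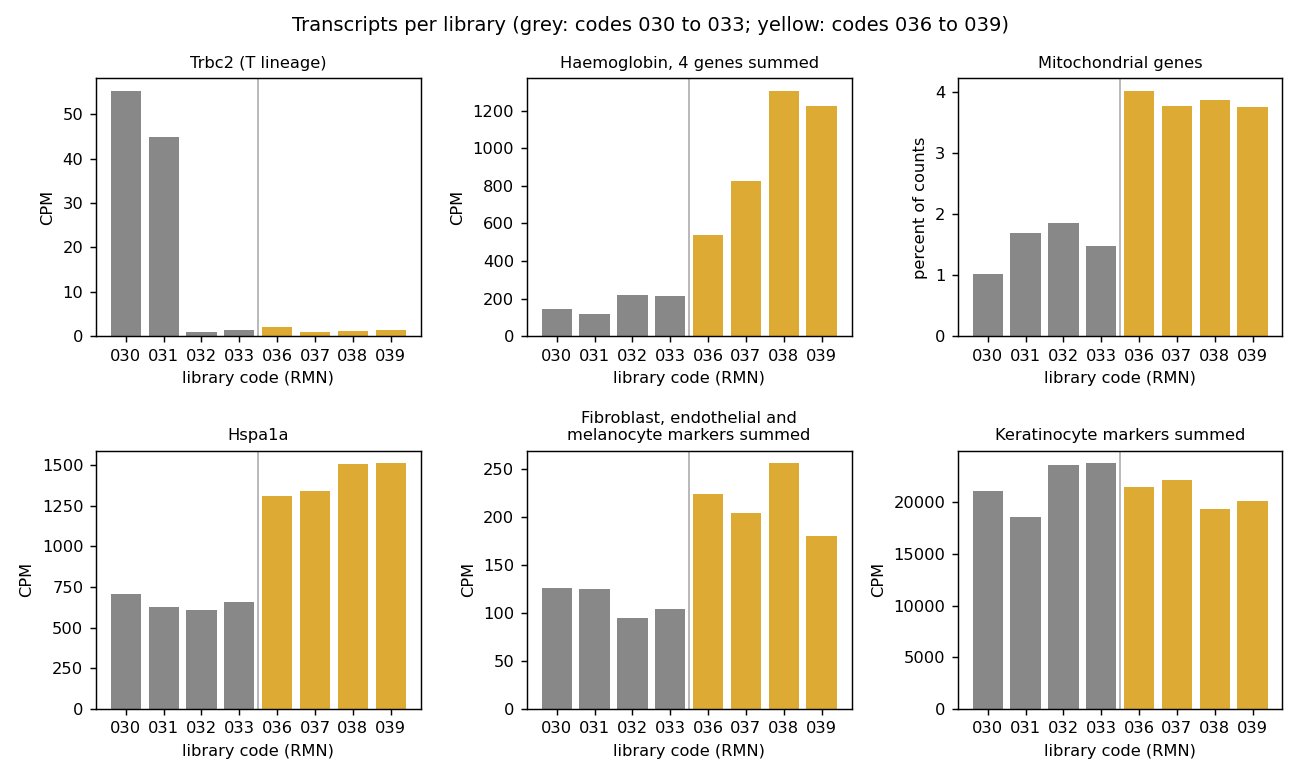
Bars give, for each library, the CPM of Trbc2, the summed CPM of 4 haemoglobin genes, the percent of counts from mitochondrial genes, the CPM of Hspa1a and the summed CPM of stromal and of keratinocyte marker lists; grey bars are the earlier library codes and yellow bars the later ones. Trbc2 is high in RMN030 (55.3 CPM) and RMN031 (44.9 CPM), and the mitochondrial share lies between 1.02 and 1.87% in the earlier and between 3.76 and 4.03% in the later codes.

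Under the title codes the migration and adhesion lists showed no call. In the adhesion list the largest evidence was for Tns1, a tensin of focal adhesions (49.3 ± 5.2 against 72.4 ± 6.7 CPM, SD, n = 4 each, adjusted p = 0.701), the only 1 of 35 members past the threshold when adjusted over the list alone. Icam1 had a log2 fold change of 0.25 (SE 0.11) and the actin nucleator gene Diaph1 one of -0.41 (SE 0.11). Among Langerhans cell identity genes, Mfge8 was at 5267 ± 432 CPM in WT and 4207 ± 200 in KO (adjusted p = 0.973). MHC class I genes, which present antigen to CD8 T cells, were all lower in sign (0 of 22 positive, 0 called, and 0 adjusted over the list alone), with a median log2 fold change of -0.13 and a camera adjusted p of 0.00288 (adjusted p = 0.618 with an estimated correlation). Among them Tap1 had a log2 fold change of -0.29 (SE 0.11) and H2-K1 one of -0.16 (SE 0.08). Interferon-stimulated genes had a camera adjusted p of 0.0432 (adjusted p = 0.328 with an estimated correlation), 8 of 30 members positive and 0 called, also adjusted over the list alone; Oas1a was at 27.8 ± 6.4 CPM in WT and 19.0 ± 2.9 in KO. T cell markers also moved lower (camera adjusted p = 3.8e-06; adjusted p = 0.328 with an estimated correlation), with 0 of 10 members called and 7 lower adjusted over the list alone. Their transcripts sat in RMN030 and RMN031: Trbc2 was at 55.3 and 44.9 CPM there and at 2.15 CPM or less in the other libraries.

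By title code, no gene of 14630 passed the threshold in edgeR, with 672 genes at an unadjusted p under 0.05 where chance gives 731.5. DESeq2 called 19 genes, 10 higher and 9 lower, and limma voom called 0. Within the earlier code run alone, 57 genes passed, 51 of them lower in KO, and 22 were in the T cell or T lineage lists; within the later run 0 passed. With the code run as a covariate 0 passed (smallest edgeR adjusted p = 0.0552). That fit had 900 genes at an unadjusted p under 0.05, above the 731.5 of chance. Each title group spans both code runs, so without the covariate the run difference adds to the spread within groups. The count of 672 is therefore no evidence that the title groups do not differ.

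By description code, KO libraries, which are the later codes, held more mitochondrial and haemoglobin transcripts. Of 14630 genes 296 passed, 209 higher and 87 lower. Mitochondrial genes were higher: mt-Co3, mt-Co1, mt-Co2, mt-Nd5 and mt-Ts1 by 2.65-, 2.69-, 2.42-, 2.59- and 2.85-fold. Hspa1a was at 650.4 ± 42.7 CPM in WT and 1419 ± 108 in KO (SD, n = 4 each). Hspa1b was 2.22-fold higher, Klf5, an epithelial transcription factor, 2.09-fold, and Hbb-bt and Hbb-bs 5.87- and 5.84-fold. Lower in KO were Nr4a1, an immediate early nuclear receptor gene (1709 ± 148 against 955 ± 62 CPM), Fos (1.39-fold), Btg2 (1.41-fold), the interleukin 1 beta gene Il1b (1.51-fold) and Ccrl2, a chemerin-binding receptor gene (1.89-fold). Ptger3, a prostaglandin E2 receptor gene, was 2.06-fold lower, and Depp1, Ccn1, Foxred2 and Rassf5 were 3.92-, 1.84-, 2.49- and 1.56-fold lower. The dissociation response list, which holds Hspa1a, Hspa1b and Nr4a1, had 2 higher and 5 lower of 32 members. Adjusted over the list alone, 3 were higher and 10 lower (camera adjusted p = 0.332).

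A total of 6 lists passed the camera test under the description codes, each in the direction of higher levels in KO, and none passed with an estimated correlation. Blood markers had 5 of 7 members called, and 5 adjusted over the list alone (adjusted p = 1.6e-08; adjusted p = 0.0594 with an estimated correlation), Alas2 at 7.33-fold among them. Mast cell and granulocyte markers had 4 of 7, and 5 adjusted over the list alone (adjusted p = 6.6e-05; adjusted p = 0.0502 with an estimated correlation): the mast cell protease genes Mcpt4 (16.5-fold), Cma1 (7.07-fold), Tpsb2 (5.67-fold) and Cpa3 (13.7-fold). Fibroblast, endothelial and melanocyte markers had 4 of 12, and 6 adjusted over the list alone (adjusted p = 1.7e-04; adjusted p = 0.0502 with an estimated correlation), with Sparc 3.20-fold and the collagen genes Col1a2 3.17-fold and Col1a1 2.25-fold higher. Monocyte and macrophage markers had 4 of 21 higher and 1 lower, and 9 higher and 4 lower adjusted over the list alone (adjusted p = 0.00346; adjusted p = 0.649 with an estimated correlation), with Lyz2 at 2.22-fold. Cholesterol genes had 1 higher and 1 lower of 25, and 7 higher and 1 lower adjusted over the list alone (adjusted p = 4.9e-04; adjusted p = 0.328 with an estimated correlation): Insig1, which restrains sterol synthesis, was at 61.7 CPM in WT and 89.7 in KO, and the mevalonate pathway gene Pmvk was 1.34-fold lower. The dendritic cell migration list had 3 of 31 higher, and 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.0404; adjusted p = 0.157 with an estimated correlation): the actin-bundling gene Fscn1 (3.06-fold), Samsn1 (2.91-fold) and Traf1 (1.55-fold). Inflammation genes went both ways (2 higher and 3 lower of 27, and 4 higher and 9 lower adjusted over the list alone), with the chemokine genes Cxcl2 lower (458 against 297 CPM) and Ccl9 5.28-fold higher, and the NF-kB inhibitor gene Tnfaip3 1.22-fold lower. In the keratinocyte list Krt79 (2.16-fold) and Krt1 (1.82-fold) were higher and Krt15 (1.37-fold) and Trp63 (1.67-fold) lower (4 of 24, and 5 higher and 2 lower adjusted over the list alone). In the actin list Fscn1 and the GTPase gene Rhob (2.18-fold) were higher (2 of 39, and 5 adjusted over the list alone). The TGF-beta receptor gene Tgfbr2 was 1.41-fold and the integrin gene Itgb8 4.32-fold higher (2 of 25 TGF-beta list members, and 2 adjusted over the list alone), and Itgb8 did not pass with limma voom (adjusted p = 0.102). Of 15 PRC2 genes 0 passed in edgeR, and 1 was higher and 1 lower adjusted over the list alone. Jarid2 was lower and missed the threshold (104 ± 6.3 against 77.4 ± 6.9 CPM, edgeR adjusted p = 0.0763, DESeq2 adjusted p = 0.0107). Rbbp7 moved the other way (log2 fold change 0.31, edgeR adjusted p = 0.139, DESeq2 adjusted p = 0.0341). The mitochondrial share was 1.51 ± 0.37% in WT and 3.86 ± 0.13% in KO and summed haemoglobin 175 ± 50 and 974 ± 357 CPM (SD, n = 4 each), and genotype here is the code run. DESeq2 called 660 genes. Without RMN033 edgeR called 140 genes, and without RMN032, RMN036, RMN037, RMN038 or RMN039 172, 155, 193, 164 and 177. Col1a2, Col1a1, Insig1, Pmvk, Traf1, Ccl9, Tnfaip3, Krt1, Trp63, Tgfbr2 and Itgb8 lost their call without at least 1 of the libraries. Krt79 lost its call without both RMN030 and RMN031 (log2 fold change 0.90, adjusted p = 0.101).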

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

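In this part, only the count of sample splits for the description-code reading was set as a test before its result was seen; the other tests were chosen after.

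Among 188 groups of 4 libraries examined, 7 held a library far from its group, where chance gives about 1 in 20, or 9.4 groups. All 7 arose under the description codes, under which more genes were examined (53 against 25 by title code). Title groups also span both code runs, which widens their range and makes a far library harder to find. Ezh2 in RMN031 was at 22.4 CPM against 14.9 to 15.7 in the other 3 WT libraries. In WT, RMN030 was low in mt-Ts1 (98.8 CPM) and in Samsn1 (2.67 CPM). In KO, RMN037 was high in mt-Co2 (767 CPM), RMN038 in Dcn (58.6 CPM), RMN039 in Krt15 (1120 CPM) and RMN036 in Jarid2 (87.7 CPM). The effect of genotype by title code differed between the code runs, by an edgeR interaction test over 16146 genes, for 3 genes, named after their values were seen: Trbc1 (adjusted p = 0.0375), Trbc2 (adjusted p = 0.0375) and Syt13 (adjusted p = 0.0418; 6.26 and 5.39 CPM in RMN030 and RMN031, 0.0613 and 0 in RMN032 and RMN033, 0 in RMN036 and RMN037, 1.14 and 1.45 in RMN038 and RMN039).

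Of 35 splits of the 8 libraries into 4 and 4, the description-code split, with 296 genes, was the 1 that called as many. The highest of the others called 0. A share of 1 in 35 is under the 0.05 set beforehand, but it does not exclude chance. Every other split mixes earlier and later codes, so the run difference adds to the spread within its groups and lowers its count. The description-code split is also the split of the earlier from the later library codes, and no within-run value can be had. For the title codes all 35 splits reached the count of 0, with 296 the highest of the others. Any split reaches a count of 0, so this says nothing about chance for the title groups. The split with 296 genes follows the code runs, which points to a structure of the samples other than the title groups.

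The first pattern is the genes called in the undisputed libraries with 20 T lineage genes left out. In the 4 disputed libraries, 12 of the 92 such genes tested there (13.04%) moved as genotype by title code would require. The other 80 (87.0%) moved with the code run (exact binomial p = 1.7e-13), which argues against title genotype as their source. That p counts the genes as independent, although sets such as the haemoglobin genes moved together. It therefore overstates the evidence and does not measure the spread between the 4 libraries. The share of 87.0% is what both the code run and the genotype by description would give. These cannot be told apart, because they are the same split. Ezh2, in contrast, parted without overlap by title code and not by description code. The margin was narrow: by title code the lowest WT library was at 15.7 CPM (RMN030) and the highest KO library at 15.2 CPM (RMN032). By title code its log2 fold change was -0.37 (SE 0.26) within the earlier and -0.63 (SE 0.26) within the later code run. Which labels hold stays open.

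The second pattern is the T lineage transcripts in RMN030 and RMN031. The 20 called T lineage genes summed to 364 and 376 CPM there and to between 13.6 and 18.9 CPM in the 6 other libraries. The other WT libraries of either reading held at most 4.86% of that level, which argues against WT genotype as the source. RNA of developing T cells may contribute. Of 26 thymocyte genes, 13 (50%) were over 10 times higher in both libraries. This is short of the 80% set for this source and not below the bound that would exclude it. The share cannot decide, because 9 of the 26 are also in the T cell list and others such as Bcl11b were expressed in every library. Members chosen after their values were seen went with this source. Dntt and Cd8b1 (18.3 and 18.7 CPM in RMN030 and RMN031) were at 0 in the 6 other libraries. Rag1 was at 7.79 and 13.3 CPM there and at 0.316 CPM or less elsewhere. Ptcra did not, at 0.305 and 0.539 CPM there and 0.543 in RMN039. How far this source contributes stays open. The sort required MHC class II and EpCAM, but whether it removed developing T cells was not tested.

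The third pattern is keratinocyte transcripts in every library: Krt14 averaged 7810 ± 831 CPM (SD, n = 8) beside 10732 ± 712 CPM of the Langerhans cell gene Cd207, although the sort required CD45. Of 25 keratinocyte genes 18 (72.0%) lay among the most abundant 10% of detected genes, as keratinocyte RNA in the libraries would give; Krtdap, a gene of differentiated cells, was at 7.19 ± 1.56 CPM. Camera, which tests for a shift in a common direction, called the list in neither reading (smaller adjusted p = 0.252). The list sum, in which abundant genes weigh most, stayed between 1.86% and 2.38% of counts. Single members did differ by description code, 2 higher and 2 lower of 24. The mixed fry test, which allows both directions, gave an adjusted p of 5.9e-08 by description code, a split that is also the code run. By title code the mixed fry adjusted p was 0.792. Keratin expression by Langerhans cells themselves was not tested.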

How the results depend on the processing

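The fits without RMN030 and RMN031, without T lineage genes and within each code run were chosen after the data were seen. Undisputed libraries: 440 genes without a filter, 305 with DESeq2, 263 to 629 with 1 library left out, and 89 without T lineage genes, against 117. Title codes: 1 without a filter, 19 with DESeq2 and 57 in the earlier code run alone, against 0; each library left out gave 0. Description codes: 660 with DESeq2 and 140 to 219 with 1 library left out, against 296, and 226 without RMN030 and RMN031. The Ezh2 log2 fold change ranged from -0.88 to -0.41 in the undisputed libraries, from -0.56 to -0.40 by title code and from -0.28 to 0.0097 by description code with 1 library left out; by description code it turned positive without RMN031 (0.0097) and without RMN030 and RMN031 (0.049). By title code Tln1 turned positive without those libraries (0.032). The cause was not tested. Replicate numbers did not pair the libraries: same-numbered deviations correlated at 0.071, 0.053, 0.085 and 0.10 by title code and between -0.0052 and 0.032 by description code, and RMN030 correlated best with another number. With the replicate block, 0 genes passed by title code and 174 by description code, and Ezh2 was at -0.49 and -0.16. Gene lists: with an estimated correlation 0 passed in each fit; fry called 4 (directional) and 16 (mixed) in the undisputed libraries, 0 and 0 by title code, and 4 and 15 by description code. Of 33 named calls in the undisputed libraries, 4 were lost without some library (Lum, Nr4a1, Trp63, Rac1); of 49 by description code, 11 were lost (Col1a2, Col1a1, Insig1, Pmvk, Traf1, Ccl9, Tnfaip3, Krt1, Trp63, Tgfbr2, Itgb8). Without RMN030 and RMN031, Insig1, Pmvk, Krt79, Tgfbr2, Itgb8 and Ccnd2 lost theirs by description code. With the block Col1a2, Col1a1, Insig1, Pmvk, Traf1, Tnfaip3, Trp63 and Itgb8 did, as did Pmvk with RLE size factors and Col1a2 without a filter; Nr4a1 lost its call in the undisputed libraries without T lineage genes. Over all alternatives of the named genes, 385 of 411 values in the undisputed libraries, 440 of 450 by title code and 708 of 795 by description code kept their direction and side of the threshold. At 11051402 to 18966195 counts per library, 1 CPM is under 20 counts, which limits genes of low level.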

Other observations

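The test of clock genes in this part was chosen after the result was seen. The 19 genes that DESeq2 called by title code were chosen after their values were seen and were not called by edgeR. Higher in KO by that reading were the immediate early gene Egr1 (log2 fold change 0.45), the phospholipase gene Plcb4 (2.14), the steroid-metabolising gene Akr1c18 (1.25) and Tns1 (0.55). The replication licensing gene Mcm2 was lower (-0.72), as was Kdelr3, a receptor that returns proteins to the endoplasmic reticulum (-1.59).

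Lists not called in any fit are given in the order undisputed, title-code and description-code, as camera adjusted p. PRC2 had 0.856, 0.694 and 0.674, its targets 0.882, 0.672 and 0.446, Langerhans cell identity 0.856, 0.535 and 0.695, adhesion 0.856, 0.446 and 0.768, and actin 0.856, 0.190 and 0.199. Of the 54 listed PRC2 targets, 27 were among the deposited genes, and only 8, 7 and 7 were tested in these fits. The values for the targets therefore say nothing about the listed targets that were not tested. MHC class II had 0.964, 0.0945 and 0.372, TGF-beta 0.163, 0.110 and 0.477, inflammation 0.525, 0.205 and 0.249, cell cycle 0.508, 0.0502 and 0.695, and apoptosis 0.777, 0.446 and 0.205. The dissociation response had 0.856, 0.0530 and 0.332, glycolysis 0.703, 0.520 and 0.695, oxidative phosphorylation 0.546, 0.251 and 0.695, keratinocyte markers 0.224, 0.446 and 0.252, and dermal dendritic cells 0.308, 0.672 and 0.768. Of the sex list only Xist was tested, with a log2 fold change between -0.06 and 0.06 in the 3 fits.

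Dbp was at 2.67 ± 0.68 CPM in the earlier and 7.13 ± 1.73 in the later codes and Nr1d1 at 62.6 ± 11.4 and 90.2 ± 9.0, while Cry2 was at 58.8 ± 7.5 and 35.04 ± 2.06 (SD, n = 4 each). As these are circadian clock genes, another hour of tissue collection might explain them. Over 8 other clock output genes minus 5 opposite-phase genes, the later codes exceeded the earlier by 0.275 in log2 (exact permutation p = 0.0571), which neither meets nor excludes that hypothesis. The output genes went both ways (from -0.30 in Per1 to 0.92 in Bhlhe41, in log2), and the widest difference of an opposite-phase gene was in Npas2 (-1.49).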
